A study of Solanum lycopersicum with 20 samples.

How the data were processed

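RNA of roots and leaves of 10-day-old Micro-Tom tomato seedlings was hybridized to 20 Affymetrix tomato arrays after 2 rounds of amplification, 1 biotin-labelled sample per array. Samples were grouped by organ and by the treatment in their titles, which gave 10 groups of 2 arrays: control, carbon nanotubes at 50, 100 and 200 µg/ml, and activated carbon at 50 µg/ml, in each organ. For 3 of the 4 activated carbon samples 1 descriptive label names nanotubes at 50 µg/ml, while the title and the protocol label name activated carbon, and the title was followed. The series title gives the activated carbon dose in mg/ml and the sample labels in µg/ml, and the sample labels were followed. The design text speaks of root tips and the sample labels of roots.

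The deposited values are intensities on a linear scale, made by the authors with GCOS, whose version and probe-set summary are not stated. The deposited table holds 10209 probe sets, and each array had been scaled by the authors so that its 2% trimmed mean is 500 (500.06 to 500.12 as measured). The comparisons, gene lists, rule for naming genes and alternatives were set before the data were examined, except where stated. By a rule set then, that scaling was to be kept only if array medians lay within 0.25 on the log2 scale. They spanned 0.305 in roots and 0.353 in leaves, so log2(value + 1) was quantile-normalized in limma across the arrays of each model, and the authors' scaling as deposited became an alternative. The 108 control and 63 reporter probe sets took part in the normalization and were then left out. A probe set was tested if at least 2 arrays of the model lay above the 40th percentile of all values, a rule that does not look at groups. Fold changes against a group whose mean, or the mean of one of its treatments, lay below the 95th percentile of the reporter probe sets are given as lower bounds against that percentile.

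Gene symbols came from the annotation of the array, brought to current names through gene identifiers where these matched (885 of 909 probe sets with a symbol). The other 9129 tomato probe sets carry no gene name and enter only the counts. No genome positions are given, since the array annotation holds none. The members of the 18 gene lists were assigned by symbol once the symbols were known but before any test. The seed storage list had 0 members and the aquaporin list 2, so 16 lists with at least 5 measured probe sets could be tested in roots, fewer in leaves.

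Each organ was fitted by its own model with 5 groups of 2 arrays (5 residual degrees of freedom), with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3. Contrasts of group means were tested two-sided, and p-values were adjusted by Benjamini-Hochberg over all probe sets tested, with 0.05 as the threshold. The average over nanotube doses weights the 3 doses equally. The comparison of control organs and the tests of whether the organs responded differently came from a model of all 20 arrays (10 residual degrees of freedom). Nanotube arrays against the others were fitted as a design of 2 groups. Errors beside changes are standard errors of the model. Nothing states whether the 2 samples of a group came from separate cultures, so p-values measure only the spread between samples. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from each list, adjusted over the lists of a comparison. Of 25 list calls in the comparisons planned for lists, none held with an estimated correlation. Counts adjusted over the list alone use only the p-values of the list's members.

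Named genes were chosen by rule. Among probe sets past the threshold with a gene name and with every array of one side above every array of the other, these were up to 12 largest rises and 12 largest falls in the main comparisons, and up to 5 each way in the others. Added to these were up to 4 members of each list by smallest p, both aquaporins, and up to 10 genes by smallest p where fewer than 5 passed. Of the genes chosen, those with the largest changes and those of the lists that moved are given with values.

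The models were tested on simulated data with the same design. Of 2-fold changes, 86% were recovered in roots and 78% in leaves for the average over nanotube doses, and 78% and 64% for activated carbon against control. Recovery was 50% in leaves at 200 µg/ml, against control and against 50 µg/ml. For the differences in response between organs it was 46% with nanotubes and 28% with activated carbon. With no change put in, 0 or 1 probe set was called per comparison within an organ, and with changes put in the false share was 3.48% to 10.7%. The simulated noise was independent between probe sets and arrays and held no differences in array quality, so false calls in the measured data can be more frequent.

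Other settings tried were the authors' scaling as deposited, centring of the log2 deposited values on array medians in place of quantile normalization, no filter, a filter at the 60th percentile, a pseudocount of 32, eBayes without the trend, a minimum of 2-fold, the replicate number as a block, each array left out in turn, and 1 model across all 20 arrays. Added after the data were seen were the mean log2 ratio of 3' to 5' signal of actin, GAPDH and EF1a as a term in leaves and in the model of all 20 arrays, and the mean level of the photosynthesis list as a term in roots. A list of shoot meristem genes was also written after the change of KN1 had been seen, and a list of leaf genes outside the plastid after the control leaf intensities but before the root values.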

Results

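Transcript levels were measured on 20 Affymetrix tomato arrays, each hybridized with RNA of roots or leaves of Micro-Tom tomato seedlings. The seedlings had grown for 10 days on medium without additive (control), with multi-wall carbon nanotubes (CNT) at 50, 100 or 200 µg/ml, or with activated carbon (AC) at 50 µg/ml. Activated carbon served as a second carbon material that is not in the form of nanotubes. Each of the 10 groups, 5 per organ, held 2 arrays, and this small number limits the precision of every comparison. Median intensity was 159 to 196 in root arrays and 118 to 150 in leaf arrays. Between 85.8% and 88.4% of probe sets in root arrays lay above the 95th percentile of the non-tomato reporter probe sets, and 78.0% to 85.7% did in leaf arrays. The 2 arrays of a group correlated across probe sets at 0.944 to 0.988 in roots and 0.961 to 0.982 in leaves. Arrays of different groups correlated at 0.877 to 0.982 in roots and 0.772 to 0.979 in leaves. The signal at the 3' end of actin, GAPDH and EF1a transcripts exceeded that at the 5' end by a geometric mean of 1.32-fold in control roots. In leaves the same ratio was 13.8-fold in control, 6.29-fold with CNT at 50 µg/ml, 5.23-fold at 100 µg/ml, 5.57-fold at 200 µg/ml and 3.42-fold with activated carbon (n = 2 arrays each). The control arrays lay above, and the activated carbon arrays below, all nanotube arrays. Among these, the range at 100 µg/ml overlapped with those at 50 and 200 µg/ml.

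**Figure D1:**
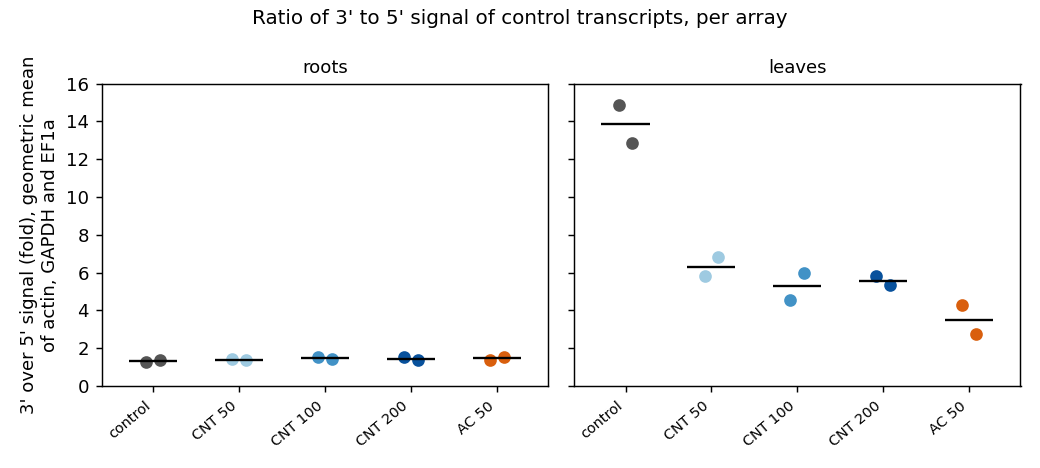
Signal at the 3' end over signal at the 5' end (fold, geometric mean of actin, GAPDH and EF1a) for each array, by treatment (CNT and AC doses in µg/ml), in roots on the left and leaves on the right. Points are arrays (n = 2 per group) and bars are means. The control leaf arrays lie at 12.9 and 14.9, above all other leaf arrays.

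The first comparison asked how untreated roots and leaves differed. Roots carried far more transcript of FER, the regulator of iron uptake (at least 166-fold, adjusted p = 1.94e-09 in limma), of the tonoplast aquaporin TIP (at least 165-fold, adjusted p = 3.27e-08) and of the metallothionein MT2 (at least 410-fold, adjusted p = 8.26e-09). The phosphate transporter PT1 (log2 difference 4.78 ± 0.17 SE) and the knotted-type homeobox gene KN1 (at least 17-fold) were also higher in roots. The aquaporin Aqp2 was higher in roots by 1.96 ± 0.32 (adjusted p = 8.99e-05). Leaves carried more of CAB5, a chlorophyll-binding protein of the light-harvesting antenna (-6.30 ± 0.86 in roots against leaves), of the subtilisin-like protease P69A (at least 20-fold) and of AGPL3, a subunit of the enzyme that commits glucose to starch (-6.37 ± 0.63). All 9 measured photosynthesis probe sets were lower in roots, with a median log2 difference of -3.59, and all 9 also passed when adjusted over the list alone (camera adjusted p = 0.0109; adjusted p = 0.934 with an estimated correlation). Of 7437 probe sets tested, 5734 differed, 3368 higher and 2366 lower in roots. HSC80, a heat shock protein with a difference of 0.77 ± 0.08, took the opposite sign under the authors' scaling as deposited (-0.17) and, with RPL37 (-0.18), when arrays were centred on their medians (-0.60). The ratio of 3' to 5' signal also differed between the organs (1.32-fold and 13.8-fold): with it as a term, chosen after the data were seen, 179 probe sets passed, FER, MT2 and PT1 among them, and the median change of the 5734 went from 1.43 (median SE 0.215) to 1.09 (median SE 1.17).

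The next comparison asked how the roots of nanotube-grown seedlings differed from control roots. THM27, a transcription factor of the MYB family, rose by 0.97 ± 0.09 on the log2 scale in the average over the 3 doses (adjusted p = 0.00673 in limma; higher in 6 of 6 nanotube arrays), from a mean intensity of 256 to 497. It rose at every dose, by 0.96 ± 0.11 at 50 µg/ml (adjusted p = 0.0123), 0.87 ± 0.11 at 100 µg/ml (adjusted p = 0.0493) and 1.09 ± 0.11 at 200 µg/ml (adjusted p = 0.0339), each against the same 2 control arrays. It did not pass at 100 µg/ml under the authors' scaling as deposited (0.83), with a pseudocount of 32 (0.79) or in a model of all 20 arrays (0.92). The same held at that dose with the photosynthesis level as a term (0.81). At 200 µg/ml it did not pass without the trend or with the replicate number as a block. With 1 of the 10 root arrays left out its call was lost in 2 cases for the average (either control array), 3 at 50 µg/ml, 8 at 100 µg/ml and 8 at 200 µg/ml. THM27 was the only gene with a name that passed at any dose. With activated carbon its log2 level was 8.43 and 8.46, above both control arrays and below every nanotube array. That difference from control did not pass. The aquaporins did not pass: Aqp2 differed by 0.21 ± 0.21 (adjusted p = 0.687) and TIP by 0.11 ± 0.08 (adjusted p = 0.540), and at single doses Aqp2 ranged from -0.15 ± 0.25 at 200 µg/ml to 0.49 ± 0.25 at 100 µg/ml. Among other genes that did not pass, the phosphate transporter PT2 differed by -1.12 ± 0.24 (adjusted p = 0.156), the metallothionein MTA by 0.75 ± 0.17 (adjusted p = 0.164) and the B-type cyclin CycB2 by -0.63 ± 0.15 (adjusted p = 0.168).

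The average over doses gave 6 of 6515 probe sets past the threshold, 5 higher and 1 lower, with 932 at an unadjusted p under 0.05 where 326 would be expected by chance. Single doses gave 23 (9 higher, 14 lower) at 50 µg/ml, 10 (7 higher, 3 lower) at 100 µg/ml and 3 (all higher) at 200 µg/ml. Cell cycle and histone genes were lower as a list at 50 µg/ml (median -0.15 over 15 probe sets, camera adjusted p = 0.0362; adjusted p = 0.594 with an estimated correlation) and at 100 µg/ml (median -0.18, camera adjusted p = 0.0406; adjusted p = 0.555 with an estimated correlation). None of the 15 passed alone, while 3 and 4 of them passed when adjusted over the list alone, all lower. At 100 µg/ml the 9 photosynthesis probe sets (median 1.3, camera adjusted p = 0.00253) and the 39 cell wall probe sets (median 0.24, camera adjusted p = 0.00258) were higher as lists, both with adjusted p = 0.555 with an estimated correlation. No member of these lists passed over all probe sets, and adjusted over the list alone 0 photosynthesis and 3 cell wall probe sets passed, 2 higher and 1 lower. The mean level of the photosynthesis list spread widely between root replicates, at 9.69 ± 0.96 (log2, SD, n = 2) in control and 11.15 ± 0.70 at 100 µg/ml. Leaf tissue in the root samples may be a source of this list's rise, as taken up below, since leaf genes outside the plastid were also high in replicate 2 at 100 µg/ml. Without control replicate 1 of the roots no probe set passed in the average over doses, at 100 µg/ml or at 200 µg/ml, and without nanotube replicate 1 at 50 µg/ml none did at that dose. Centred on medians 11 passed in the average and 4 at 100 µg/ml. Under the authors' scaling as deposited 3 at 100 and 7 at 200 µg/ml passed, and in a model of all 20 arrays 1 in the average and 0 at 100 µg/ml.

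**Figure D2:**
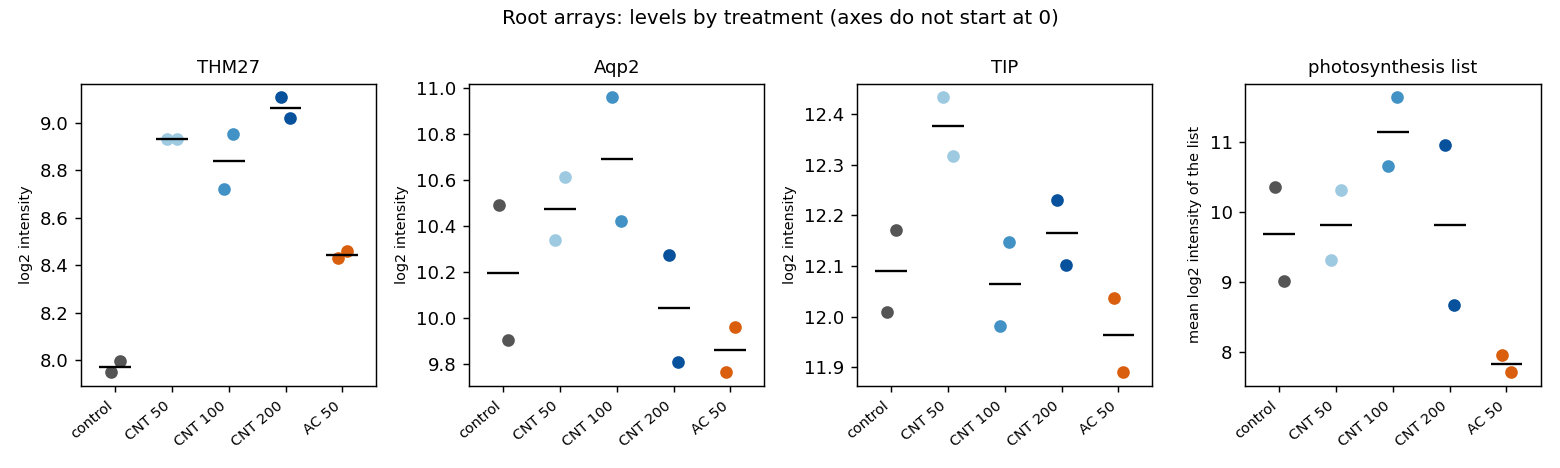
Level (log2 intensity after quantile normalization) of THM27, Aqp2 and TIP, and mean log2 intensity of the 9 photosynthesis probe sets, in each root array by treatment (CNT and AC doses in µg/ml). Points are arrays (n = 2 per group), bars are means, and the axes do not start at 0. THM27 lies at 7.95 and 8.0 in control, at 8.43 and 8.46 with activated carbon and at 8.72 or above in every nanotube array.

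Activated carbon was compared with control to ask what carbon that is not in nanotubes does to roots. No gene with a name passed in limma, and the nearest were PR1b1, a pathogenesis-related protein (-2.04 ± 0.30, adjusted p = 0.0590), the polyphenol oxidase LOC606710 (1.18 ± 0.17, adjusted p = 0.0590) and the invertase inhibitor CIF1 (-0.59 ± 0.10, adjusted p = 0.0773). As lists, the 9 photosynthesis probe sets (median -1.56), the 8 pathogenesis-related probe sets (median -0.55) and the 39 ethylene probe sets (median -0.18) were lower, with camera adjusted p = 0.000157, 0.000157 and 0.00641. In the same order these were adjusted p = 0.534, 0.458 and 0.534 with an estimated correlation. Adjusted over the list alone, 1 photosynthesis, 4 pathogenesis-related and 1 ethylene probe set passed, all lower. The photosynthesis list had its lowest level in these arrays, 7.84 ± 0.17 (log2, SD, n = 2). In total 5 probe sets passed, 2 higher and 3 lower, and 1242 had an unadjusted p under 0.05. Under the authors' scaling as deposited 83 passed (9 higher, 74 lower), centred on medians 42 (22 higher, 20 lower) and in a model of all 20 arrays 21 (3 higher, 18 lower). The count was 0 without activated carbon replicate 2.

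At 50 µg/ml both materials were used, so their roots could be compared without the control. Nanotube roots were higher than activated carbon roots in CAB5 (3.72 ± 1.02, adjusted p = 0.0439), the expansin EXPA4, which loosens cell walls (1.97 ± 0.28, adjusted p = 0.00710), PR1b1 (1.91 ± 0.30, adjusted p = 0.00876) and the hydroperoxide lyase HPL (1.54 ± 0.22, adjusted p = 0.00692). They were lower in LOC543757 (-3.78 ± 0.52, adjusted p = 0.00692), the polyphenol oxidase LOC606710 (-1.3 ± 0.17, adjusted p = 0.00670) and PT2 (-1.25 ± 0.29, adjusted p = 0.0279). The aquaporin TIP was higher with nanotubes by 0.41 ± 0.09 (adjusted p = 0.0243), a call lost under the authors' scaling as deposited (0.18) and when centred on medians (0.018), while Aqp2, at 0.61 ± 0.25, did not pass (adjusted p = 0.135). Of 15 cell cycle and histone probe sets 4 were lower, namely CYCD3 (-0.67 ± 0.09), PCNA, the sliding clamp of DNA replication (-0.68 ± 0.11), CycB2 (-1.0 ± 0.18) and CycA1 (-0.85 ± 0.21), and adjusted over the list alone 5 were. Of 9 photosynthesis probe sets 2 were higher (4 adjusted over the list alone), of 8 pathogenesis-related ones 2 (4 adjusted over the list alone), and of 39 ethylene ones 7 were higher and 1 lower (11 and 1 adjusted over the list alone).

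As lists, photosynthesis (camera adjusted p = 0.00659), pathogenesis-related and ethylene genes (both 0.0349) were higher and cell cycle genes lower (0.0412) with nanotubes, each with adjusted p = 0.457 with an estimated correlation. In total 1026 probe sets differed, 464 higher and 562 lower with nanotubes, 214 of them by at least 2-fold. Without nanotube replicate 1 the count was 14, and under the authors' scaling as deposited 61.1% of the probe sets that passed were higher instead of 45.2%, centred on medians 30.8%. In a model of all 20 arrays 528 passed, 302 of them higher. When the level of the photosynthesis list was added to the model as a term, chosen after the data were seen, 180 probe sets passed, 151 of them among the 1026.

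The highest and lowest nanotube doses were compared to ask whether the root response changed with dose. At 200 µg/ml roots carried more of the dehydrin TAS14 than at 50 µg/ml (2.32 ± 0.39, adjusted p = 0.0406) and more of LOC543757 (3.37 ± 0.52, adjusted p = 0.0335). They carried less of the expansin EXP12 (-1.23 ± 0.19, adjusted p = 0.0335) and of the beta-galactosidase TBG3 (-1.11 ± 0.20, adjusted p = 0.0431). Of 39 cell wall probe sets these 2 passed, 4 did when adjusted over the list alone, all lower, and the list as a whole was lower (median -0.30, camera adjusted p = 0.00322; adjusted p = 0.561 with an estimated correlation). In total 79 probe sets differed, 61 higher and 18 lower at 200 µg/ml, and none did without replicate 1 of the 50 µg/ml roots. Centred on medians 66 were higher and 9 lower, and the count was 49 with a pseudocount of 32, 24 without the trend and 50 in a model of all 20 arrays.

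All 6 nanotube root arrays were also set against the 4 root arrays without nanotubes. This design counts arrays of the same treatment as independent samples, so its p-values can be too small. THM27 (0.74 ± 0.12, adjusted p = 0.0391) and the beta-galactosidase TBG4 (0.82 ± 0.15, adjusted p = 0.0422) were higher with nanotubes. PT2 (-1.23 ± 0.18, adjusted p = 0.0391), CycB2 (-0.73 ± 0.14, adjusted p = 0.0422), PCNA (-0.52 ± 0.11, adjusted p = 0.0499) and the ribosomal protein gene RPL8 (-0.24 ± 0.05, adjusted p = 0.0422) were lower. The photosynthesis list was higher (median 1.24, camera adjusted p = 0.00110, and 0.530 with an estimated correlation) with no member past the threshold, also when adjusted over the list alone. Its mean log2 level was 9.69 in control, 9.82 at 50 µg/ml, 11.15 at 100 µg/ml, 9.82 at 200 µg/ml and 7.84 with activated carbon. The list difference therefore rests mainly on the activated carbon and 100 µg/ml roots. The comparison gave 86 probe sets, 27 higher and 59 lower. It gave 27 (10 higher, 17 lower) under the authors' scaling as deposited, 13 (8 higher, 5 lower) centred on medians, 47 without the trend and 6 without the filter, where of the genes named here PT2 alone passed. The count was 0 without replicate 1 of the activated carbon roots and 0 with the level of the photosynthesis list as a term. Nearly all of the calls were also lost with the replicate number as a block.

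**Figure D3:**
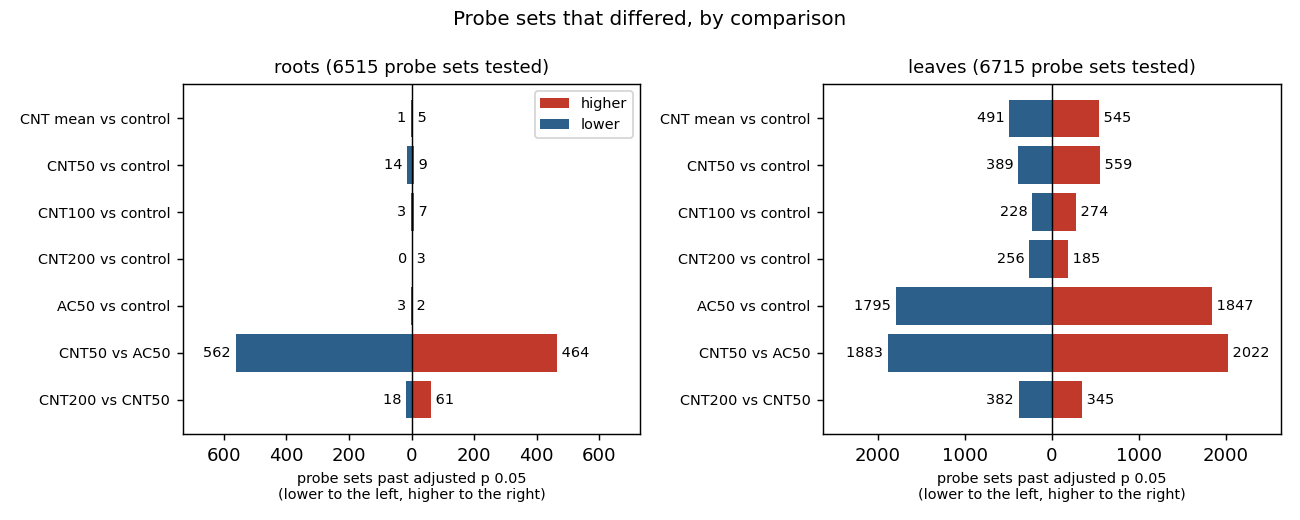
Number of probe sets past adjusted p 0.05 in each comparison, higher to the right and lower to the left, in roots (left panel) and leaves (right panel), whose axes differ. CNT mean is the average over the 3 nanotube doses. Leaves with activated carbon against control gave 1847 higher and 1795 lower, and roots gave 2 higher and 3 lower.

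In leaves, nanotube-grown seedlings were again compared with control. GluB, a basic beta-1,3-glucanase, rose by 1.93 ± 0.28 (adjusted p = 0.00659 in limma), the chitinase CHI9 by 0.85 ± 0.16 (adjusted p = 0.0134) and EREB by 2.55 ± 0.50 (adjusted p = 0.0152). EREB belongs to the ethylene list, of whose 35 probe sets 4 were higher and 2 lower (6 and 2 adjusted over the list alone). The alternative oxidase AOX1a, which bypasses part of the mitochondrial electron transport chain, rose by 1.19 ± 0.19 (adjusted p = 0.00956), the expansin exp9 by 1.32 ± 0.31 (adjusted p = 0.0268) and the hexose transporter HT1 by 0.95 ± 0.17 (adjusted p = 0.0125). The cell wall enzyme tXET-B2 was at least 9.97-fold lower (adjusted p = 0.0125), and at 200 µg/ml it lay below the reporter background. The arginase ARG2 fell by 1.56 ± 0.31 (adjusted p = 0.0162). Aqp2 was 0.58 ± 0.27 higher and did not pass (adjusted p = 0.169), and TIP was below the filter in leaves.

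Of 7 measured pathogenesis-related probe sets 4 rose (GluB, CHI9, and the subtilisin-like proteases P69A and P69B), also when adjusted over the list alone, and the list was higher as a whole (median 0.85, camera adjusted p = 0.020; adjusted p = 0.832 with an estimated correlation). ACO6, an enzyme of the last step of ethylene synthesis, rose by 1.31 ± 0.21 and 0.79 ± 0.14 in 2 of its 3 probe sets, and the other gave 0.10 ± 0.12 (adjusted p = 0.582). The heat shock gene Hsp90-1 rose by 0.69 ± 0.17 (adjusted p = 0.0289). The photosynthesis genes CAB5 (0.20 ± 0.09) and PSBP (0.10 ± 0.09) did not pass, and both were negative under the authors' scaling as deposited (-0.51 and -0.56). In total 1036 of 6715 probe sets differed, 545 higher and 491 lower, among them 55 higher and 30 lower with a gene name. Under the authors' scaling as deposited 1641 passed, 1126 higher and 515 lower, and in a model of all 20 arrays 1566. The control leaf arrays had the highest ratio of 3' to 5' signal: with this ratio as a term in the model, chosen after the data were seen, no probe set passed, and without replicate 1 of the control leaves 24 did.

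At single doses 948 probe sets passed at 50 µg/ml (559 higher, 389 lower), 502 at 100 µg/ml (274 higher, 228 lower) and 441 at 200 µg/ml (185 higher, 256 lower). Of these, 66 were higher and 53 lower at all 3 doses, against the same control arrays. ER1, whose function the annotation does not give, rose by 2.18 ± 0.22 at 50 µg/ml (adjusted p = 0.00314) and 3.03 ± 0.22 at 100 µg/ml (adjusted p = 0.00140). GluB rose by 2.35 ± 0.34 (adjusted p = 0.00848) and 2.69 ± 0.34 (adjusted p = 0.0145), and CHI9 by 1.32 ± 0.20 (adjusted p = 0.00880) and 1.37 ± 0.20 (adjusted p = 0.0145), at the same doses. At 200 µg/ml these 3 did not pass (ER1 0.16 ± 0.22, GluB 0.76 ± 0.34, CHI9 -0.13 ± 0.20). At 50 µg/ml 2 of 7 pathogenesis-related probe sets rose, 3 adjusted over the list alone (camera adjusted p = 0.0298; adjusted p = 0.843 with an estimated correlation), and at 100 µg/ml 3 did, also adjusted over the list alone (camera adjusted p = 0.00246; adjusted p = 0.667 with an estimated correlation). At 200 µg/ml the phosphate-starvation gene TPSI1 rose by 1.61 ± 0.28 (adjusted p = 0.0156) and the NAC-domain transcription factor NAC1 fell by 2.75 ± 0.32 (adjusted p = 0.00295), as did the ethylene response factors ERF4 by 1.27 ± 0.18 (adjusted p = 0.00585) and PTI4 by 1.13 ± 0.20 (adjusted p = 0.0147). With the ratio of 3' to 5' signal as a term no probe set passed at any dose. In dose order the counts were 1328 (920 higher, 408 lower), 952 (637 higher, 315 lower) and 991 (625 higher, 366 lower) under the authors' scaling as deposited. In a model of all 20 arrays they were 1470, 1005 (634 higher, 371 lower) and 1156 (687 higher, 469 lower). Centred on medians they were 901 (380 higher, 521 lower) at 100 and 773 (308 higher, 465 lower) at 200 µg/ml. The counts fell to 29 at 50 µg/ml without its replicate 1, to 1 at 100 µg/ml without control replicate 1, and to 57 at 200 µg/ml without its replicate 1.

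Activated carbon against control gave the largest number of differences from control in either organ. The pathogenesis-related genes NP24-I, an osmotin-like protein (-5.85 ± 0.69, adjusted p = 0.000311 in limma), GluB (-5.70 ± 0.34, adjusted p = 3.04e-05), LOC543878, of the PR5 family (-5.35 ± 0.50, adjusted p = 0.000137), and CHI9 (-2.95 ± 0.20, adjusted p = 3.64e-05) fell. ER1 was at least 22.8-fold lower (adjusted p = 5.19e-07) and lay below the reporter background. Genes of cell division rose: CycB2 by 3.22 ± 0.73 (adjusted p = 0.00537), PCNA by 2.79 ± 0.50 (adjusted p = 0.00174) and the cyclin-dependent kinase CDKB2 by 2.46 ± 0.67 (adjusted p = 0.0131). The anthocyanin enzyme DFR rose by 3.52 ± 0.99 (adjusted p = 0.0146), the proline-rich protein TPRP-F1 by 5.57 ± 1.42 (adjusted p = 0.00941) and Aqp2 by 2.13 ± 0.33 (adjusted p = 0.000993), from an intensity of 256 to 1119.

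Of 7 pathogenesis-related probe sets 5 fell, also adjusted over the list alone, with a list median of -2.95 (camera adjusted p = 0.0141). Of 35 ethylene probe sets 24 fell and 1 rose, also adjusted over the list alone, with a median of -0.84 (camera adjusted p = 3.85e-05). Among them were ERF4 (fell by 2.73 ± 0.18), PTI4 (fell by 2.36 ± 0.20) and ACO6, which fell in all 3 of its probe sets, by 1.47 ± 0.15 to 2.74 ± 0.17. Of 10 dehydration and abscisic acid probe sets 6 fell and 1 rose (7 and 1 adjusted over the list alone, median -1.05, camera adjusted p = 0.0152), including ZEP, an enzyme on the path to abscisic acid (fell by 1.93 ± 0.18). Of 19 sugar and starch probe sets 12 fell and 3 rose (13 and 3 adjusted over the list alone, median -0.73, camera adjusted p = 0.0468), with sucrose phosphate synthase SPS falling by 1.40 ± 0.25 and the invertase inhibitor CIF1 by 1.66 ± 0.18. Of 15 cell cycle and histone probe sets 9 rose and 1 fell, also adjusted over the list alone (median 0.82, camera adjusted p = 0.0468), and of 6 cytosolic ribosome probe sets 5 rose, all 6 adjusted over the list alone (median 0.92, camera adjusted p = 0.0238). Each of these 6 lists had adjusted p = 0.370 with an estimated correlation. The heat shock gene Hsp90-1 rose by 1.97 ± 0.21 (adjusted p = 0.000183).

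In total 3642 probe sets differed, 1847 higher and 1795 lower, with 140 higher and 231 lower among those with a gene name. The ratio of 3' to 5' signal was 3.42-fold with activated carbon and 13.8-fold in control, and with this ratio as a term, chosen after the data were seen, no probe set passed. The median change of the 3642 went from 1.04 (median SE 0.210) to 0.7501 (median SE 0.741). The error grew more than the change fell, and what is left of the change is not told apart from its error. TPRP-F1, the dUTPase gene P18 and the chaperonin gene CPN21 took the opposite sign.

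**Figure D4:**
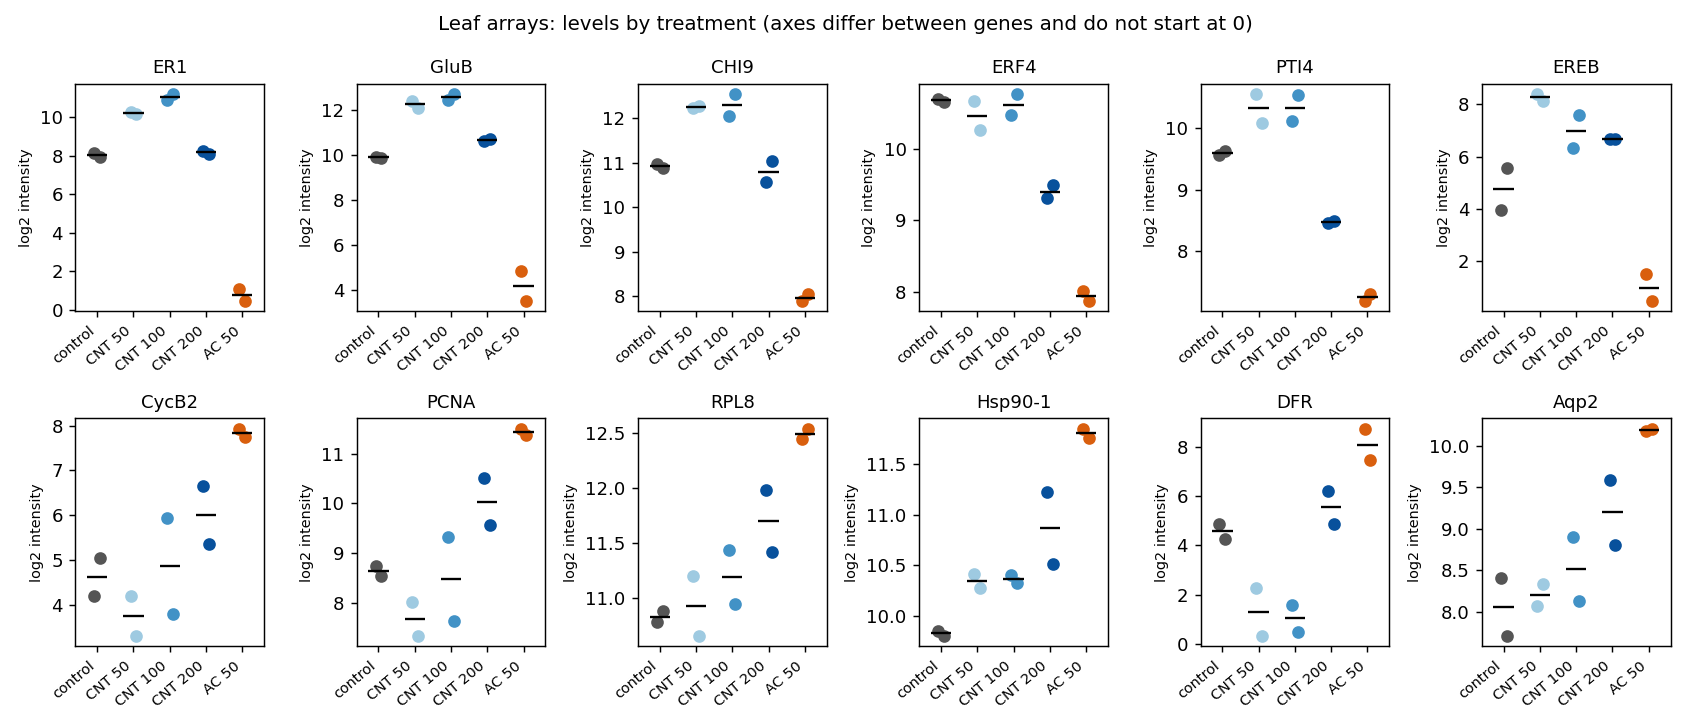
Level (log2 intensity after quantile normalization) of 12 genes in each leaf array by treatment (CNT and AC doses in µg/ml). Points are arrays (n = 2 per group) and bars are means, and axes differ between genes and do not start at 0. Aqp2 averages 8.06 in control, 9.20 with CNT at 200 µg/ml and 10.19 with activated carbon, and PCNA averages 8.6, 10.0 and 11.4 in the same groups.

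Set directly against each other at 50 µg/ml, leaves with nanotubes and with activated carbon differed in more probe sets than either did from control. GluB was higher with nanotubes by 8.05 ± 0.34 (adjusted p = 4.73e-06 in limma), NP24-I by 7.45 ± 0.69 (adjusted p = 6.71e-05), LOC543878 by 6.32 ± 0.50 (adjusted p = 4.19e-05) and CHI9 by 4.27 ± 0.20 (adjusted p = 5.28e-06). ER1 was at least 103-fold higher and EREB at least 26.6-fold higher. PCNA (-3.75 ± 0.50, adjusted p = 0.000305) and Aqp2 (-1.99 ± 0.33, adjusted p = 0.000985) were lower with nanotubes. TPRP-F1 (at least 142-fold, adjusted p = 0.00105), DFR (at least 19.5-fold) and CycB2 (at least 13.6-fold, adjusted p = 0.00130) were also lower.

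The lists moved with these genes: 5 of 7 pathogenesis-related probe sets (median 4.27, camera adjusted p = 0.00272) and 25 of 35 ethylene probe sets (median 1.09, camera adjusted p = 1.3e-05) were higher with nanotubes, and 2 ethylene probe sets were lower. Of 19 sugar and starch probe sets 12 were higher and 2 lower (12 and 3 adjusted over the list alone, median 0.99, camera adjusted p = 0.0249). Of 15 cell cycle probe sets 10 were lower and 1 higher (median -1.94, camera adjusted p = 0.0249), and all 6 cytosolic ribosome probe sets were lower (median -1.26, camera adjusted p = 0.0105). For the lists other than sugar and starch the counts were the same adjusted over the list alone, and each of the 5 lists had adjusted p = 0.427 with an estimated correlation. In total 3905 probe sets differed, 2022 higher and 1883 lower with nanotubes, and 2952 or more did whichever array was left out. The ratio of 3' to 5' signal was 6.29-fold with nanotubes and 3.42-fold with activated carbon, and with this ratio as a term 1466 probe sets passed, 1399 of them among the 3905.

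Between the highest and lowest nanotube dose, leaves at 200 µg/ml carried more of the cell cycle genes CycA1 (2.34 ± 0.48, adjusted p = 0.0280), PCNA (2.35 ± 0.50, adjusted p = 0.0288) and CYCD3 (1.5 ± 0.31, adjusted p = 0.0282) and of TPRP-F1 (at least 35.2-fold, adjusted p = 0.0316). They carried less of PTI4 (-1.85 ± 0.20, adjusted p = 0.0139), ER1 (-2.03 ± 0.22, adjusted p = 0.0139), CHI9 (-1.45 ± 0.20, adjusted p = 0.0139) and GluB (-1.59 ± 0.34, adjusted p = 0.0298). Of 35 ethylene probe sets 9 were lower (12 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000314). Of 15 cell cycle probe sets 3 were higher (6 adjusted over the list alone; camera adjusted p = 0.0394), and of 6 ribosome probe sets 1 was (5 adjusted over the list alone; camera adjusted p = 0.00919). These 3 lists had adjusted p = 0.427 with an estimated correlation. In total 727 probe sets differed, 345 higher and 382 lower, and none did without replicate 1 of the leaves at 200 µg/ml. The count was 481 without the filter, 393 without the trend, 1403 in a model of all 20 arrays and 266 with the ratio of 3' to 5' signal as a term.

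The 6 nanotube leaf arrays against the 4 without nanotubes gave 77 probe sets, 61 higher and 16 lower. As in roots, arrays of the same treatment count as independent samples here, so the p-values can be too small. EREB (at least 8.26-fold, adjusted p = 0.0464), HT1 (1.33 ± 0.26, adjusted p = 0.0461), the expansin EXP2 (1.26 ± 0.26, adjusted p = 0.0483) and PT1 (1.20 ± 0.24, adjusted p = 0.0464) were higher with nanotubes, and no named gene was lower. The pathogenesis-related list was higher (median 2.33, camera adjusted p = 0.00102; adjusted p = 0.431 with an estimated correlation) with 0 of 7 probe sets past the threshold and 6 adjusted over the list alone. The ethylene list (median 0.55, camera adjusted p = 0.00102) and the sugar and starch list (median 0.38, camera adjusted p = 0.0291) were also higher, both with adjusted p = 0.584 with an estimated correlation, and with 1 probe set each past the threshold. Adjusted over the list alone, 9 ethylene probe sets were higher and 1 lower, and 2 sugar and starch probe sets were higher. These lists fell in activated carbon leaves against control, as given above. Since those leaves are part of the side without nanotubes, the list differences are not of nanotubes against control alone. The number of probe sets was 352 (319 higher, 33 lower) under the authors' scaling as deposited, 129 (89 higher, 40 lower) centred on medians and 29 without the filter, where none of the 4 genes named here passed. The count was 7 without replicate 2 of the leaves at 50 µg/ml, and 2627 with the ratio of 3' to 5' signal as a term. That ratio was highest in control and lowest with activated carbon, both on the side without nanotubes, so the larger count is not read as an effect of nanotubes. Most of the calls were lost with the replicate number as a block.

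The last comparisons tested whether roots and leaves responded differently. For nanotubes, averaged over doses, THM27 differed between the organs by 0.94 ± 0.19 (roots minus leaves, adjusted p = 0.0204 in limma), GluB by -1.63 ± 0.41 (adjusted p = 0.0394) and ER1 by -1.57 ± 0.22 (adjusted p = 0.00459). For activated carbon, NP24-I differed by 5.17 ± 0.85 (adjusted p = 0.00134), GluB by 4.92 ± 0.50 (adjusted p = 0.000110) and LOC543878 by 4.67 ± 0.55 (adjusted p = 0.000309). The nanotube response differed in 369 of 7437 probe sets, 100 with a more positive and 269 with a more negative change in roots, and the activated carbon response in 2177, 928 and 1249 in the same order. Without replicate 1 of the control roots the counts were 22 and 1307, and under the authors' scaling as deposited the count for nanotubes was 964, 160 and 804 in the same order, and centred on medians 528, 239 and 289. The leaf side of these differences goes with a 3' to 5' ratio of 13.8-fold in control leaves against 5.23 to 6.29-fold with nanotubes and 3.42-fold with activated carbon. With the ratio as a term, chosen after the data were seen, 1 and 2 probe sets passed, ER1 in both, and NP24-I took the opposite sign (-0.81).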

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

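Of the tests in this part, the comparison of the 2 control leaf replicates with either left out, the shading test, the shoot meristem test, the values raised to background, the splits that keep groups together and the models with an added term were chosen after the result was seen.

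The response to nanotubes differed between roots and leaves, by a test of the difference itself (roots minus leaves, log2), in 369 probe sets. Among the named genes the model's fitted differences were positive in LOC543717 (3.605, adjusted p = 0.0164 in limma), tXET-B2 (2.80), TBG3 (1.27), Asc-1 (1.23) and THM27 (0.94). They were negative in LOC543892 (-3.79, adjusted p = 0.00457), EREB (-3.09), EXP1 (-1.71), GluB (-1.63) and ER1 (-1.57). For 4 of these genes a group mean lay below the reporter background, and with values below it raised to it the differences were 3.045 (LOC543717), 2.415 (tXET-B2), -0.484 (LOC543892) and -0.758 (EXP1). THM27 changed by 1.03 in roots and 0.09 in leaves, and GluB by 0.14 and 1.77. Without replicate 1 of the control roots the count was 22. With the 3' to 5' ratio, which in leaves goes with the treatment, as a term, 1 probe set passed, and the median change went from 0.901 (median SE 0.201) to 0.580 (median SE 0.428), so a difference in response between the organs is not separated from that ratio.

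The response to activated carbon differed between the organs in 2177 probe sets. The fitted differences were positive in ER1 (6.70, adjusted p = 9.72e-09 in limma), NP24-I (5.17), GluB (4.92), LOC543878 (4.67) and LOC543717 (4.28). They were negative in DFR (-6.09, adjusted p = 0.0204), TPRP-F1 (-5.43), LOC543899 (-5.38), KN1 (-5.05) and LOC543656 (-4.09). For 5 of these genes a group mean lay below the reporter background, so the fitted values are not measured sizes. With values below background raised to it they were 3.808 (ER1), -3.762 (DFR), -3.472 (LOC543899), -1.606 (KN1) and -1.684 (LOC543656). Without replicate 1 of the control roots the count was 1307. With the 3' to 5' ratio as a term 2 passed, and the median change went from 1.17 (median SE 0.273) to 0.646 (median SE 0.722).

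The leaf differences between nanotube and control seedlings rest on control leaves whose 3' to 5' ratio was 13.8-fold. A slope on that ratio within groups predicts a median of 0.363 of the measured change, with 2 of 32 sign flips as high, so loss of 5' signal in the control leaves may account for part of it and cannot be told apart from the treatment, because the ratio goes with the groups. With the ratio as a term the median change went from 0.752 (median SE 0.164) to 0.481 (median SE 0.451). The error grew more than the change fell, and what is left of the change is not told apart from its error. That control replicate 1 alone made the differences was tested first over the probe sets called against both controls. There a median of 0.916 of the change was left against replicate 2. The change is taken against the mean of these 2 controls, whose median gap was 0.193 in these probe sets and 0.177 in the others. Over the probe sets called against both controls, these values argue against replicate 1 alone as the source. A later test on the probe sets called without replicate 2 left 0.539, between the limits set for it, so a larger part of those calls may come from replicate 1. Calls made on replicate 1 alone also carry its error, which lowers this share. With replicate 1 left out instead, a median of 0.942 was left against replicate 1. A response to nanotubes stays open and untested.

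For the leaf differences between activated carbon and 50 µg/ml nanotubes, the slope on the 3' to 5' ratio within groups predicted a median share of 0.0503. With a group left out the share was -0.0851 to 0.226. Sign flips of the within-group differences gave shares of -0.227 to 0.227, 14 of 32 as high. A ratio that made the differences would give a large share with the real signs, and these did not. The shares lay under the limit set beforehand against this cause, also with any group left out. Over the 3905 called probe sets they argue against loss of 5' signal as the main source of the change. A smaller part stays open. With the ratio as a term the median change was 1.06 (median SE 0.371) instead of 1.11 (median SE 0.210), and 1466 probe sets passed. Whether the activated carbon leaf samples held shoot apex tissue is not decided. As measured, 8 probe sets of 7 shoot meristem genes were a median of 2.67 higher, with 0 of 10000 random sets as high, but many values lay below background. Raised to it, the median was 0.350. It was 0.108 without KN1, whose change had been seen before the list was written, with 767 of 10000 random sets as high. That background was 3.527 with activated carbon and 3.795 with nanotubes (log2), so a probe set below it in both, such as LS, counted as -0.27 and lowered the median. All 8 lie below the filter in leaves, 6 of them above the reporter background in both activated carbon arrays and 0 in either nanotube array. A younger leaf stage, which would raise cell cycle genes too, and a response to activated carbon stay open, as untested.

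Photosynthesis genes varied between root samples, from a mean log2 level of 7.84 with activated carbon to 11.15 with nanotubes at 100 µg/ml. Leaf tissue in the root samples may be the source: leaf genes outside the plastid implied a share of leaf signal that was a median of 0.573 of the share implied by the photosynthesis list. Both shares take the activated carbon roots as free of leaf signal, which was not tested. Between arrays this ratio ran from 0.260 (control replicate 1) to 1.52 (50 µg/ml nanotubes, replicate 1). In nanotube replicate 2 at 100 µg/ml the 2 shares were 12% and 14.3%, but in control replicate 1 they were 1.52% and 5.84%, so part of the signal may be of the roots. Shading by either carbon material would lower the list at 50 µg/ml of nanotubes too, where its median change was 0.0579, within the spread between replicates, so it cannot be told apart from no shading.

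The comparison of nanotube arrays with the others called 86 probe sets in roots, and 3 of 100 splits drawn from the 210 possible called as many, the real one included, with 642 as the highest other. In leaves it called 77, and 2 of 100 did, with 1387 as the highest other. These shares would exclude chance only if the 2 arrays of a group were as independent as arrays of different groups, since most splits part them. The 10 splits that keep both arrays of each group together are too few for a share under 0.05. Of these, 2 in roots and 3 in leaves called as many, the real one included, with 213 and 2335 as the highest other. Splits that call many times the real number point to a structure of the samples: in leaves the highest of these set the nanotube arrays at 200 µg/ml and the activated carbon arrays against the rest.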

How the results depend on the processing

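The added terms (level of the photosynthesis list in roots, 3' to 5' ratio in leaves and across organs) were the tests in this part chosen after the data were seen. CNT-grown is the comparison of all nanotube arrays with the others, CNT mean the average over doses, and other names are doses in µg/ml against control unless stated. The cause of each change below was not tested, except that a 2-fold minimum can only lower a count.

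The authors' scaling as deposited gave, in roots, 27 (CNT-grown), 3 (CNT100), 7 (CNT200) and 83 (AC50) probe sets, in leaves 352 (CNT-grown), 1641 (CNT mean), 952 (CNT100) and 991 (CNT200), and 964 for the organ difference with nanotubes. It moved the median of all probe sets in leaf CNT mean by 0.15. Median centring gave, in roots, 13 (CNT-grown), 11 (CNT mean), 4 (CNT100) and 42 (AC50), and in leaves 129 (CNT-grown), 901 (CNT100) and 773 (CNT200). No filter gave 6 (roots CNT-grown), 29 (leaves CNT-grown) and 481 (leaves CNT200 against CNT50). A pseudocount of 32 gave 2 (roots CNT100) and 49 (roots CNT200 against CNT50). Without the trend the counts were 47 (roots CNT-grown), 0 (roots CNT200), 24 (roots CNT200 against CNT50) and 393 (leaves CNT200 against CNT50). No count moved by over 1.5 times with a filter at the 60th percentile.

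A minimum of 2-fold left, in roots, 3 (CNT-grown), 3 (CNT mean), 5 (CNT100) and 214 (CNT50 against AC50). In leaves it left 45 (CNT-grown), 296 (CNT mean), 399 (CNT50), 221 (CNT100), 244 (CNT200), 1918 (AC50), 2233 (CNT50 against AC50) and 344 (CNT200 against CNT50), and 153 and 1349 for the organ differences with nanotubes and activated carbon. The replicate number as a block gave, in roots, 1 (CNT-grown), 14 (CNT50), 2 (CNT100), 0 (CNT200) and 32 (CNT200 against CNT50), and 21 in leaves CNT-grown. Between groups, the differences of replicate 1 from replicate 2 correlated from -0.447 to 0.247 in roots (over 0.1 in 4 of 10 pairs of groups) and -0.207 to 0.348 in leaves (over 0.1 in 5 of 10, among them the 3 pairs of nanotube doses), so the numbers are not taken to pair the samples across all groups. A model across all 20 arrays gave, in roots, 1 (CNT mean), 0 (CNT100), 21 (AC50), 528 (CNT50 against AC50) and 50 (CNT200 against CNT50), and in leaves 1566 (CNT mean), 1470 (CNT50), 1005 (CNT100), 1156 (CNT200) and 1403 (CNT200 against CNT50).

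The photosynthesis level as a term gave 0 (roots CNT-grown), 0 (roots CNT100) and 180 (roots CNT50 against AC50). The 3' to 5' ratio as a term gave 0 for each of CNT mean, CNT50, CNT100, CNT200 and AC50 in leaves, 1466 (CNT50 against AC50), 266 (CNT200 against CNT50) and 2627 (CNT-grown), and across organs 179 (control roots against control leaves), 1 (organ difference with nanotubes) and 2 (with activated carbon). Of 25 gene list shifts 0 passed with an estimated correlation.

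Genes that reversed with median centring were NP24-I (-0.062) and LEMT1 (-0.12) in roots CNT50 against AC50, CAB5 (-0.65) and PSBP (-0.70) in leaves CNT mean, CAB5 (-0.72) in leaves CNT100, and HSC80 (-0.60) and RPL37 (-0.18) between control organs. With the authors' scaling as deposited these were CAB5 (-0.51) and PSBP (-0.56) in leaves CNT mean, CAB5 (-0.55) in leaves CNT100, and HSC80 (-0.17) between control organs. With the 3' to 5' ratio as a term these were MT4 in leaves CNT mean (-0.25) and CNT50 (-0.084), ARG2 in CNT200 (0.000323), and TPRP-F1 (-1.91), P18 (-0.040) and CPN21 (-0.53) with AC50. In the organ difference with AC50 they were NP24-I (-0.81) and TPRP-F1 (2.03), and between control organs TPRP-F1 (-4.15), Mdip1 (-4.91), AG1 (0.98), P69B (1.15), H1 (-1.2), hqt (-0.0083) and RPL3 (-0.025).

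With each array left out in turn, the lone array of its group being assumed to vary like the other groups, root counts ran from 0 to 542 (CNT-grown), 0 to 12 (CNT mean), 0 to 71 (CNT50), 0 to 56 (CNT100), 0 to 14 (CNT200), 0 to 80 (AC50), 14 to 1358 (CNT50 against AC50) and 0 to 101 (CNT200 against CNT50). Leaf counts ran from 7 to 413 (CNT-grown), 24 to 1068 (CNT mean), 29 to 1218 (CNT50), 1 to 456 (CNT100), 57 to 768 (CNT200) and 0 to 1167 (CNT200 against CNT50). The organ differences ran from 22 to 715 and from 1307 to 2334. Counts within 1.5 times of the reported one throughout were leaves AC50 (2659 to 3734), leaves CNT50 against AC50 (2952 to 3959) and control roots against control leaves (5263 to 5798). Signal over background limits leaves more than roots, since down to 78.0% of probe sets lay above the reporter background.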

Other observations

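Of the tests in this part, the choices without activated carbon arrays and the shift of the highest nanotube dose toward activated carbon were chosen after the result was seen.

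Whether activated carbon changed the same genes in both organs was tested across the 3172 probe sets called in leaves and measured in roots. Their changes correlated at r = 0.409 across genes, with the same sign in 77.6%. Of 1260 choices of 2 against 2 root arrays, 131 gave a correlation as high, up to 0.625 in another choice. The limit set before the result was seen, over 5% of other choices, does not decide, because many choices hold activated carbon arrays on one side and would carry a shared response too. Of the 420 choices without activated carbon arrays 12 gave a correlation as high, up to 0.488, so a response shared by both organs stays open.

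At the highest nanotube dose the leaf profile may shift toward that of activated carbon, or may lose changes shared by the lower doses. The differences of 200 against 100 µg/ml nanotubes correlated with those of activated carbon against 50 µg/ml nanotubes at r = 0.724 across genes (slope 0.315), and these share no array. With 50 and 100 µg/ml exchanged the correlation was 0.814 (slope 0.463). Both differences subtract a lower nanotube dose. The changes at 50 and 100 µg/ml against the same controls correlated at 0.820 (simulated with no effect 0.497). A return toward control at 200 µg/ml would therefore raise both correlations too, and they do not tell it from a shift toward activated carbon. A difference in the tissue sampled stays open, as untested.

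Comparisons against the same controls share part of their error, so the covariance of their log2 changes is given beside that of simulations with shared controls and no effect. In leaves it was 0.300 for 50 and 100 µg/ml nanotubes, where simulations gave 0.0396, 0.204 for 50 and 200 µg/ml (simulated 0.0397) and 0.219 for 100 and 200 µg/ml (simulated 0.0395). In the same order 226, 88 and 75 probe sets were higher and 142, 109 and 64 lower in both, where independent lists would share 22.8, 15.4 and 7.55 higher and 13.2, 14.8 and 8.69 lower. In leaves 1 probe set moved in opposite directions at 50 and 200 µg/ml. Nanotubes on average and activated carbon in leaves had a covariance of 0.246 (simulated 0.0395) and a correlation of 0.416 (simulated 0.609), with 256 probe sets higher and 322 lower in both, against 150 and 131 for independent lists, and 81 in opposite directions. In roots the 3 pairs of doses gave 0.0368, 0.0150 and 0.0498 (simulated 0.0279, 0.0280 and 0.0277), with 4, 3 and 2 probe sets higher and 0 lower in both. Nanotubes on average and activated carbon in roots gave -0.0165 (simulated 0.0280), with 2 higher in both. The simulations put at most 1 probe set in both lists. They leave out the effects, and the independent lists leave out the shared controls, so the excess over either is not read as a shared effect alone.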
